A study of Mus musculus with 12 samples.

How the data were processed

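Ribosome footprints and total mRNA were profiled in liver of FVB/N mice, either wild type or carrying 20 copies of a mutant selenocysteine (Sec) tRNA transgene, TrspA37G. The mice were kept for 6 weeks on diets with 0, 0.1 or 2.0 ppm selenium. Per the labels, the age was 3 weeks, which is less than the time on the diets and so is not taken as the age at sampling. The labels also say that livers were frozen and homogenised with cycloheximide, footprints were made with an RNase and isolated as monosomes, and a small RNA kit was used for the libraries. The 2 genotypes, 3 diets and 2 kinds of library give 12 libraries in 12 groups of 1. How many mice went into a library is not given in the sources used here. Within a genotype and diet, the footprint and the mRNA library were matched by their labels.

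Per the submitters' processing notes, the reads were mapped with Bowtie and the mouse build was mm9. Versions, filters, read trimming and the handling of reads that map more than once are not given in the sources used here. The deposited values are in 4 tables of 23 selenoprotein genes. Per the file headers, the first table holds RPKM values, mRNA reads scaled to the length of the whole mRNA and to the mapped reads of the library. Per the file headers, the other 3 tables hold footprints (RPFKM, the same unit as RPKM counted over footprints) and mRNA (RPKM) over the coding sequence (CDS) without its first 15 and last 3 codons, over the CDS 5' of the UGA codon for Sec, and over the CDS 3' of it. In these 3 deposited tables, column 8 is called mRNA in the assay line and RPFKM in the unit line. It was read as footprints, because another column of the same group holds the mRNA values. Per these headers, the authors scaled each value to the region's length and the library's mapped reads. RPKM values share 1 total per library, so a large difference in a few abundant RNAs moves all other values of that library.

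Whole reads could be recovered from these values once 1 number of mapped reads per library had been found. All 795 values above 0 then gave a whole number of reads within 0.001. For 641 of them the length of the region came from annotated codons. Such a length was kept only where it gave whole reads, so their wholeness is no test. What could have failed is the match of the annotated lengths, given below for the CDS window. For the other 154, of which 130 are the values over whole mRNAs, the length was the smallest that gave whole reads, so wholeness is built in and the reads are the fewest possible. The annotated coding lengths came from GENCODE release M21 (build GRCm38, used for transcript structure only, since the files use mm9 and give no coordinates). The CDS window proved to be 57 nt shorter than the annotated CDS. With that length 95.3% of the CDS values came out whole, against 10.1% at the best other length tried. For 22 of the 23 genes the window matched the annotated codons. Txnrd3 needed a longer coding sequence than annotated, and its length was fitted from the values. The 5' and 3' windows leave 18 nt between them, taken to be the 6 codons ending with the UGA codon for Sec. Only the lengths of the windows were recovered, so this placement was inferred and not tested. The comparisons had been planned for counts or for normalised values. As reads could be recovered, the floor of 10 reads planned for counts was used.

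Each comparison sets 1 library against 1 other. There are no replicates of a group. A fit of genotype with diet as a block was possible and was left out, so no test across conditions was made and no p-value is given. Exchanging genotype labels within the 3 diets could not give a two-sided exact p below 0.25. A gene entered a comparison when each region used held at least 10 reads over the 2 libraries and at least 1 read in each. Its ratio is the ratio of the deposited values, with no pseudocount, and a 95% interval was made from the reads. For ratios of 2 values the interval is the exact conditional one (Clopper-Pearson). For ratios of ratios it is the exact conditional odds ratio for up to 2000 reads and a log-normal interval above that. The log-normal form was also used for differences between diet responses. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules and variation between mice is not in them. A gene is called higher or lower when its ratio is at least 1.5-fold and the interval excludes 1. Translational efficiency is the footprint value over the CDS divided by the RPKM of the whole mRNA. The readthrough ratio is the footprint density 3' of the UGA-Sec codon divided by the density 5' of it, within a library, and does not depend on the scaling of libraries. A value of 0 reads allows up to 3 reads.

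Depth was 17763406 to 30296837 mapped reads for footprints and 10669213 to 16709701 for mRNA. In reads simulated from the real ones, the mapped reads of 12 of 12 libraries and 776 of 776 values came back. The intervals were tested in up to 2000 simulated draws per fold, a number raised after a smaller first run, on the footprints of the wild-type 0.1 ppm library. For the ratio of 2 footprint values over 20 genes, a true 1.5-fold lower value was called in 46.2% of draws, a 2-fold one in 90.7% and a 4-fold one in 97.8%. For the readthrough ratio over 9 genes these shares were 49.2%, 95.1% and 99.6%. With no difference, 0.3% and 0.35% were called lower. The 95% intervals held the true ratio in 95.2% to 96.2% of draws. The draws held counting error alone, so these shares say nothing about variation between mice. The library used had the most reads over the listed coding sequences of all footprint libraries, 103282 against 24187 in TrspA37G at 0 ppm. Comparisons with fewer reads would call a smaller share of true differences.

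Genes were named by a rule set before the data were examined, as were the comparisons, the size rule, the floor and the gene lists. 12 genes are named in each comparison whatever their value: Gpx1, Gpx4, Sepw1, Sepp1, Txnrd1, Sephs2, Sepx1, Selh, Selk, Selt, Sep15 and Dio1. To these come the 10 largest differences in each direction, up to 30 genes. The lists were glutathione peroxidases with Sec, thioredoxin reductases, deiodinases, stress-related and housekeeping selenoproteins (as work on Sec tRNA mutants groups them), selenoproteins of the endoplasmic reticulum, and those with the UGA near the C terminus. The same fixed set included Sec synthesis and decoding factors, Nrf2 targets, cysteine homologues of glutathione peroxidases, hepatocyte markers and markers of other liver cell types. Of these last 5 lists the tables hold 1 of 12, 0 of 10, 0 of 4, 0 of 5 and 0 of 11 members, so they were not summarised and the cell make-up of the livers was not examined. The Sec tRNA gene itself was not analysed here, so the genotype labels were not checked against its level.

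Alternatives were a 2-fold size rule, no floor or a floor of 30 reads, a pseudocount of 1 RPKM, 2.0 ppm as the reference diet, the 5' part of the CDS, the 3' density over mRNA, readthrough without genes whose UGA is near the C terminus and without Sepp1, and scaling to the median ratio of the listed genes. All listed genes encode selenoproteins, so this scaling removes any difference they share. Chosen only after seeing the data were translational efficiency with mRNA over the CDS window, footprints and translational efficiency without the 18 nt between the windows, readthrough divided by the mRNA 3' to 5' ratio, and genotype counts without the TrspA37G 0 ppm library. Computations used Python 3.11.15, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.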

Results

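Selenocysteine (Sec) is inserted at UGA codons by a dedicated Sec tRNA. The series asks how dietary selenium affects Sec insertion and selenoprotein expression in mouse liver, with wild-type animals beside animals carrying the mutant Sec tRNA transgene TrspA37G. Ribosome footprints, which mark codons covered by ribosomes, and total mRNA were measured at 0, 0.1 and 2.0 ppm selenium, with 1 library for each genotype, diet and kind of RNA and no replicates. At 0, 0.1 and 2.0 ppm, footprint libraries held 23945053, 30296837 and 17763406 mapped reads in wild type and 28864210, 29816461 and 22139115 in TrspA37G. The mRNA libraries held 16709701, 14220047 and 12399318 in wild type and 12403067, 10669213 and 13073779 in TrspA37G. Footprints over the coding sequences of the 23 listed selenoprotein genes made up 0.156%, 0.341% and 0.458% of mapped reads in wild type and 0.0838%, 0.131% and 0.143% in TrspA37G. For mRNA these shares were 0.475%, 0.660% and 0.727%, and 0.317%, 0.460% and 0.479%. 20 genes could be compared in mRNA and footprints; Dio2, Dio3 and Gpx2 had too few reads, so that of the deiodinases only Dio1 is described.

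The genes differ in where the UGA codon for Sec lies, here given from the GRCm38 annotation. Gpx1, the cytosolic glutathione peroxidase, lies on chromosome 9 with Sec at codon 47 of 201, in exon 1 of 2. In Gpx4, the phospholipid hydroperoxide glutathione peroxidase on chromosome 10, Sec is codon 73 of 197, in exon 3 of 7. Sepp1, the selenium carrier that liver secretes into plasma, lies on chromosome 15 and has 10 Sec codons, the first of them codon 59 of 380. Sephs2, which makes the selenium donor for Sec synthesis, lies on chromosome 7 with Sec at codon 63 of 452. In Sepx1, a methionine sulfoxide reductase on chromosome 17, Sec is codon 95 of 116, and in the small redox protein Sepw1 on chromosome 7 it is codon 13 of 88. Txnrd1, the cytosolic thioredoxin reductase on chromosome 10, has Sec at codon 498 of 499.

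In wild-type liver, mRNA of 4 of 20 selenoproteins was lower without added selenium than at 0.1 ppm, and none was higher. Sepw1 mRNA was 3.04-fold lower (95% interval 2.54 to 3.66), at 13.8 against 41.9 RPKM. Gpx1 mRNA was 2.61-fold lower (2.56 to 2.66), at 893 against 2327 RPKM. Selh, a nuclear redox protein, was 2.46-fold lower (1.43 to 4.36), and Txnrd3, a thioredoxin reductase best known from testis, 1.56-fold lower (1.23 to 1.99). Of the other genes followed throughout, Gpx4 (log2 0.36), Sephs2 (0.41), Selt (0.09) and Dio1 (0.01) lay above 0, and Sepp1 (-0.39), Txnrd1 (-0.37), Sepx1 (-0.12), Selk (-0.48) and Sep15 (-0.26) below, all within 1.5-fold. Among stress-related selenoproteins 3 of 7 were lower (median log2 -0.48), among housekeeping ones 0 of 6 (-0.29), among thioredoxin reductases 1 of 3 (-0.37) and among those with the UGA near the C terminus 1 of 7 (-0.32). Of the glutathione peroxidases 1 of 3 was lower with a median of 0.23, and of the endoplasmic reticulum selenoproteins 0 of 7, with a median of -0.22 that turned positive under median-ratio scaling. The median over all 20 genes was -0.24, and scaling to it left 3 lower (Gpx1, Selh, Sepw1) and made 2 higher (Gpx4, Sephs2). Between 2.0 and 0.1 ppm, Gpx3, the plasma glutathione peroxidase, was 1.81-fold higher (1.26 to 2.64), while the 12 genes followed throughout lay between log2 -0.34 (Selk) and 0.50 (Dio1). The medians of the 6 lists ran from 0.03 to 0.12 in that comparison.

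In TrspA37G liver, 6 of 20 mRNAs were lower at 0 than at 0.1 ppm and none was higher. Dio1, the deiodinase that acts on thyroxine, was 4.68-fold lower (4.28 to 5.13), at 28.8 against 135 RPKM, where in wild type it was at 77.6 against 76.8 RPKM. Gpx1 was 3.20-fold lower (3.10 to 3.31) and Sepw1 2.45-fold lower (1.88 to 3.21). Seli, an ethanolamine phosphotransferase, was 1.96-fold lower (1.82 to 2.12), Txnrd3 1.94-fold (1.26 to 3.02) and the mitochondrial thioredoxin reductase Txnrd2 1.65-fold (1.29 to 2.10). Gpx1, Sepw1 and Txnrd3 were thus lower in both genotypes. Selh had log2 -2.22 with an interval from -5.49 to 0.11, from few reads, and Gpx4 (0.16), Sepp1 (-0.44), Txnrd1 (-0.09), Sephs2 (-0.16), Sepx1 (0.14), Selk (-0.32), Selt (-0.45) and Sep15 (-0.58) were within the 1.5-fold rule. Stress-related selenoproteins had 2 of 7 lower (median -0.63), glutathione peroxidases 1 of 3 (-0.63) and thioredoxin reductases 2 of 3 (-0.72). Housekeeping genes had 1 of 6 lower (-0.30), endoplasmic reticulum genes 1 of 7 (-0.32) and those with a late UGA 3 of 7 (-0.32), and these 3 medians turned positive under median-ratio scaling. That scaling removes a median of -0.44 and gave 3 lower (Dio1, Gpx1, Sepw1) and 2 higher (Gpx4, Sepx1). Between 2.0 and 0.1 ppm, Txnrd2 was 1.66-fold lower (1.31 to 2.12). The 12 genes lay between log2 -0.14 (Txnrd1) and 1.03 (Selh, whose interval included 0), and list medians between -0.14 and 0.09.

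**Figure D1:**
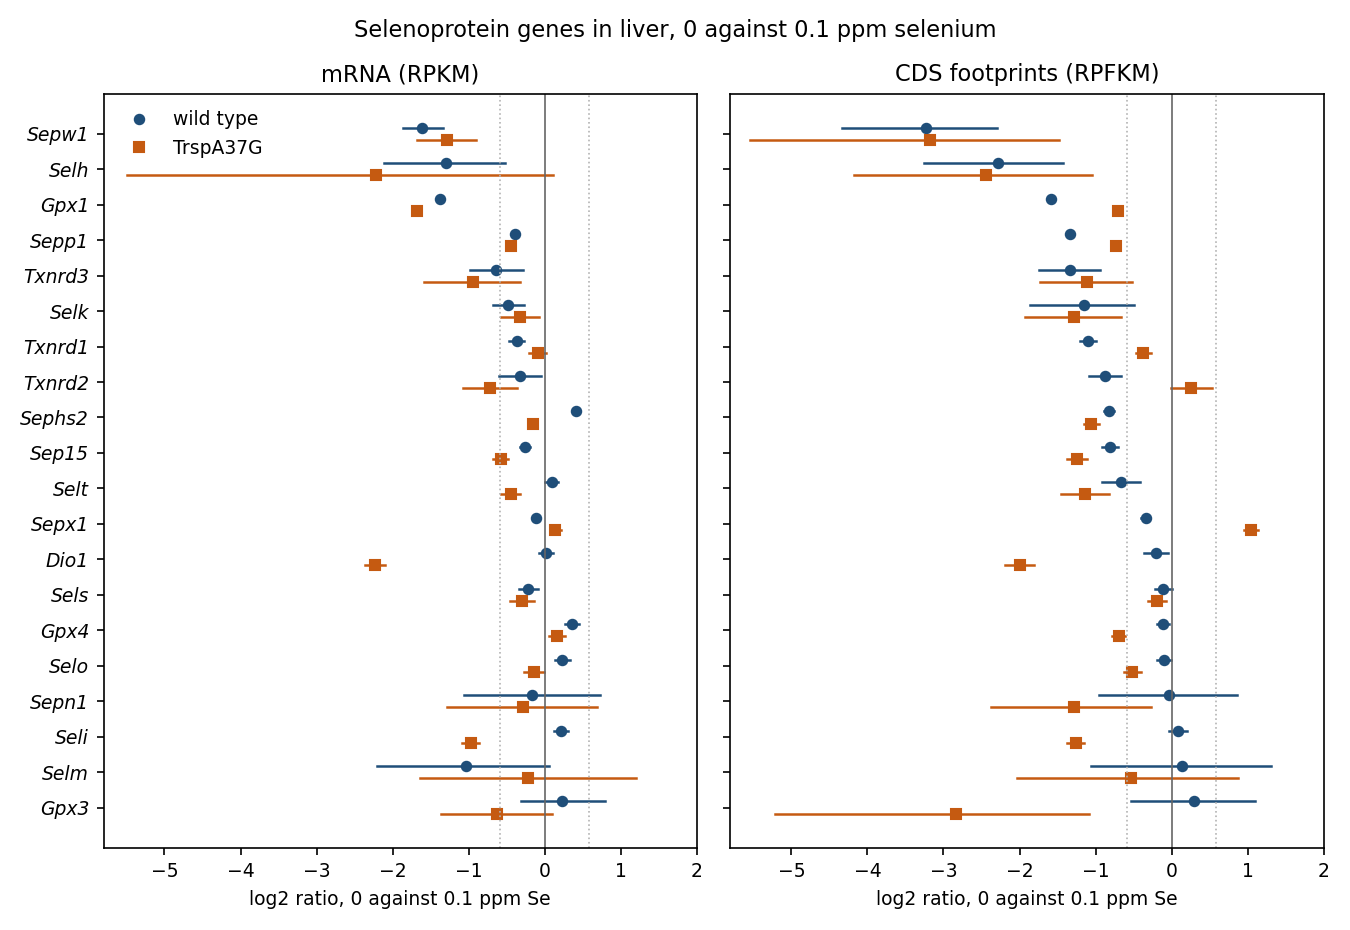
Log2 ratio of 0 to 0.1 ppm selenium for 20 selenoprotein genes, for total mRNA and for footprints over the coding sequence, in wild type and TrspA37G; points are ratios of single libraries, bars are 95% counting intervals and dotted lines mark 1.5-fold. Footprints are lower in 11 genes in wild type and 14 in TrspA37G as deposited, against 5 and 3 after median-ratio scaling.

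Between genotypes, Gpx1 mRNA was lower in TrspA37G at each diet, by 2.54-fold (2.46 to 2.63), 2.07-fold (2.03 to 2.11) and 2.06-fold (2.02 to 2.10) at 0, 0.1 and 2.0 ppm. Txnrd3 was 2.52-fold (1.72 to 3.76), 2.03-fold (1.5 to 2.77) and 2.12-fold (1.60 to 2.84) lower, and these 2 genes alone were lower in all 3 diets. Dio1 was 2.69-fold lower (2.46 to 2.95) at 0 ppm, 1.75-fold higher (1.65 to 1.87) at 0.1 ppm and within 1.5-fold (log2 0.26) at 2.0 ppm. Sepw1 was lower at 0.1 (1.80-fold, 1.51 to 2.16) and 2.0 ppm (1.66-fold, 1.42 to 1.94), and Selh at 0 (7.79-fold, 1.91 to 68.6, from 2 reads in TrspA37G) and 0.1 ppm (4.13-fold, 1.92 to 10.1). Also lower at 0 ppm were Gpx3 (1.71-fold), Seli (1.53-fold), Selo (1.55-fold), Selt (1.67-fold) and Sephs2 (1.55-fold), and at 2.0 ppm Gpx3 (1.98-fold), Sepx1 (1.68-fold) and Txnrd2 (2.04-fold). Gpx4 (-0.15, 0.05 and 0.41), Sepp1 (-0.42, -0.38 and -0.49), Txnrd1 (0.04, -0.23 and -0.37), Selk (0.00, -0.16 and 0.23) and Sep15 (-0.56, -0.24 and 0.18) were within the rule at each diet. Stress-related selenoproteins were lower in 4, 3 and 4 of 7 cases (medians -0.74, -0.54 and -0.75). Housekeeping ones were lower in 1, 0 and 1 of 6, with medians of -0.42, -0.15 and -0.30 that turned positive under median-ratio scaling. All-gene medians were -0.55, -0.23 and -0.43; the scaling that removes them gave 4, 4 and 3 lower and 1, 2 and 6 higher genes in place of 9, 4 and 6 lower and 0, 1 and 0 higher.

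Footprints over the coding sequence were lower at 0 than at 0.1 ppm for 11 of 20 genes in wild type. Sepw1 was 9.41-fold lower (4.94 to 20.1), at 2.02 against 19.0 RPFKM, and Selh 4.86-fold lower (2.69 to 9.53). The UGA of Sepw1, at codon 13, lies within the first 15 codons left out. Its footprint and efficiency values throughout therefore describe the part 3' of the UGA alone. For Txnrd1 nearly the whole window lies 5' of the UGA, with 984 of 985 footprints in wild type at 0 ppm. Lists thus join genes measured on different sides of the UGA. Gpx1 was 2.99-fold lower (2.93 to 3.05), Sepp1 2.53-fold (2.47 to 2.59) and Txnrd3 2.52-fold (1.91 to 3.36). Selk, a membrane protein of the endoplasmic reticulum, was 2.22-fold lower (1.40 to 3.62), Txnrd1 2.15-fold (2.00 to 2.31), Txnrd2 1.83-fold (1.58 to 2.11), Sephs2 1.77-fold (1.69 to 1.85), Sep15 1.75-fold (1.62 to 1.90) and Selt 1.58-fold (1.33 to 1.88). Dio1 (log2 -0.20), Gpx4 (-0.11) and Sepx1 (-0.34) were within 1.5-fold. All 3 thioredoxin reductases were lower (median -1.10), 5 of 7 stress-related (-1.15), 5 of 6 housekeeping (-0.85) and 4 of 7 selenoproteins with a late UGA (-0.87). Of 3 glutathione peroxidases 1 was lower and of 7 endoplasmic reticulum genes 3, with medians of -0.11 in both that turned positive under median-ratio scaling. That scaling removes a median of -0.73 and gave 5 lower (Gpx1, Selh, Sepp1, Sepw1, Txnrd3) and 5 higher genes (Gpx3, Gpx4, Seli, Selo, Sels), of which Gpx4, Selo and Sels had been below 0, with Selt at log2 0.08. Over the part 5' of the UGA alone, Sephs2 was at 0.33 and 6 of 19 genes were lower. At 2.0 ppm Gpx1 was 1.57-fold (1.55 to 1.59), Gpx3 2.19-fold (1.30 to 3.73) and Selh 1.51-fold (1.08 to 2.11) higher than at 0.1 ppm, of which Gpx3 alone was past the rule after scaling, which removes a median of 0.21. The other genes followed throughout lay between log2 -0.13 (Selk) and 0.54 (Sephs2) there. Lists had medians from 0.06 to 0.65 there, with 2 of 3 glutathione peroxidases and 3 of 7 stress-related genes higher as deposited.

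In TrspA37G, footprints of 14 of 20 genes were lower at 0 than at 0.1 ppm and those of 1 were higher. Sepx1 was the higher one, by 2.07-fold (1.94 to 2.21). Sepw1 was 9.04-fold lower (2.79 to 46.4) and Gpx3 7.10-fold (2.13 to 37), each from 3 reads at 0 ppm, Selh 5.42-fold (2.07 to 18) and Dio1 3.99-fold (3.50 to 4.55). Selk was 2.44-fold lower (1.59 to 3.82), Sepn1, a reductase of the endoplasmic reticulum, 2.42-fold (1.2 to 5.19), Seli 2.4-fold (2.21 to 2.60), Sep15 2.37-fold (2.16 to 2.60) and Selt 2.20-fold (1.77 to 2.75). Txnrd3 was 2.16-fold lower (1.43 to 3.31), Sephs2 2.08-fold (1.95 to 2.22), Sepp1 1.66-fold (1.61 to 1.71), Gpx1 1.63-fold (1.57 to 1.69) and Gpx4 1.62-fold (1.53 to 1.71), and Txnrd1 (log2 -0.37) was within the rule. Gpx1, Selh, Selk, Selt, Sep15, Sephs2, Sepp1, Sepw1 and Txnrd3 were lower in both genotypes, 9 in all. Of stress-related genes 6 of 7 were lower (median -1.28) and of endoplasmic reticulum genes 5 of 7 (-1.24). Glutathione peroxidases (3 of 3 lower, -0.70), thioredoxin reductases (1 of 3, -0.37), housekeeping genes (4 of 6, -0.71) and those with a late UGA (3 of 7, -0.52) had medians that turned positive under median-ratio scaling. That scaling removes a median of -1.08 and gave 3 lower (Dio1, Gpx3, Sepw1) and 4 higher (Sels, Sepx1, Txnrd1, Txnrd2) genes, of which Sels and Txnrd1 had been below 0, with Gpx1 at log2 0.38, Gpx4 at 0.39, Sepp1 at 0.35 and Sephs2 at 0.03. Between 2.0 and 0.1 ppm 0 genes were past the rule, the 12 genes lay between log2 -0.30 (Txnrd1) and 0.67 (Selh), and the all-gene median was 0.14 and list medians from -0.30 to 0.25.

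Between genotypes, footprints of Gpx1 were 3.38-fold (3.26 to 3.50), 6.21-fold (6.06 to 6.36) and 8.89-fold (8.66 to 9.14) lower in TrspA37G at 0, 0.1 and 2.0 ppm. Sepx1 was 1.83-fold (1.74 to 1.92), 4.80-fold (4.53 to 5.09) and 5.11-fold (4.76 to 5.48) lower, and Sephs2 2.52-fold (2.36 to 2.70), 2.14-fold (2.05 to 2.24) and 2.39-fold (2.28 to 2.5) lower. With Sepw1 (4.02-, 4.18- and 4.06-fold), Selh (3.13-, 2.81- and 2.68-fold) and Txnrd3 (2.34-, 2.74- and 3.16-fold) they make up the 6 genes lower in all 3 diets. Sepp1 was 1.97-fold (1.93 to 2.01) and 2.02-fold (1.97 to 2.06) lower at 0.1 and 2.0 ppm and within the rule at 0 ppm (log2 -0.37), and Txnrd2 was 2.99-fold (2.56 to 3.52) and 4.10-fold (3.37 to 5.01) lower at these diets. Lower at 0 ppm were also Dio1 (2.5-fold), Gpx3 (10.8-fold, 3.34 to 55.9, from 3 reads), Seli (1.70-fold), Selo (1.94-fold), Selt (1.99-fold) and Sep15 (1.78-fold), and at 2.0 ppm Gpx3 (2.80-fold) and Txnrd1 (1.75-fold). Gpx4 (-0.52, 0.06 and 0.32) and Selk (-0.02, 0.12 and 0.51) were within the rule at each diet. Stress-related genes were lower in 6, 4 and 5 of 7 cases (medians -1.65, -1.49 and -1.49) and glutathione peroxidases in 2, 1 and 2 of 3. Housekeeping genes were lower in 2, 3 and 4 of 6 (-0.49, -0.71 and -0.91) and thioredoxin reductases in 1, 2 and 3 of 3 (-0.45, -1.45 and -1.66), and both medians at 0 ppm turned positive under median-ratio scaling. All-gene medians were -0.96, -0.48 and -0.67; after the scaling that removes them 2, 7 and 7 genes were lower and 3, 3 and 3 higher, against 12, 8 and 10 lower and 0 higher as deposited. Gpx1 alone was then lower in all 3 diets, and at 0 ppm, of the genes lower as deposited, Seli (log2 0.20), Sep15 (0.13), Sepx1 (0.09) and Selo (0.01) changed sign. Sepp1 (from -0.37 to 0.59) and Selk (from -0.02 to 0.95) turned sign there too and were then called higher.

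Footprints in the 18 nt between the windows, taken to end with the UGA codon, weighed heavily in some of these values. They made up 69.7% to 90.2% of Gpx1's coding-sequence footprints in the 6 libraries, against 18.2% to 27.1% of its mRNA reads and 3.30% of its length. In Sepx1 the shares were 36.8% to 47.3% of footprints and 23.2% to 29.2% of mRNA reads over 6.19% of the length. In Selh they held 44 of 80 footprints in wild type at 0.1 ppm. The share of footprints was smaller than that of mRNA reads in 6 of 6 libraries for Gpx4 and in 5 of 6 for Seli. Without these nt, chosen as an alternative after seeing the data, Gpx1 footprints at 0 against 0.1 ppm were at log2 -2.99 (-3.07 to -2.91) in wild type in place of -1.58 (-1.61 to -1.55), and at -1.79 (-1.94 to -1.63) in TrspA37G in place of -0.70 (-0.76 to -0.65). At 2.0 ppm in wild type Gpx1 went from 0.65 (0.63 to 0.67) to 0.52 (0.48 to 0.55), below 1.5-fold, and Selh from 0.60 (0.12 to 1.08) to 0.46 (-0.30 to 1.2), so neither was then called. Selh at 0 ppm in wild type was at -3.25 (-5.59 to -1.58) in place of -2.28, and between genotypes at 0.1 ppm at -2.15 in place of -1.49. Outside these nt, Gpx1 footprints 3' of the UGA were at 70.6, 890 and 1105 RPFKM in wild type at 0, 0.1 and 2.0 ppm. In TrspA37G they were at 16.3, 79.8 and 110. Those 5' of it were at 359, 946 and 2316 in wild type and at 99.5, 207 and 304 in TrspA37G. The size of the Gpx1 difference between genotypes thus depended on the part of the coding sequence.

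**Figure D2:**
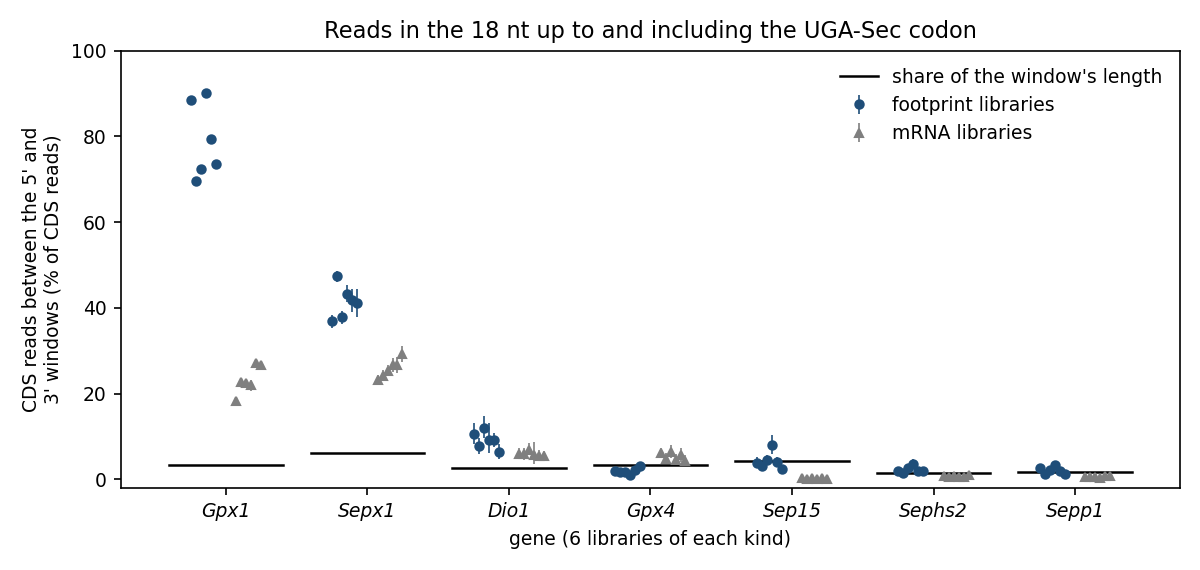
Share of coding-sequence reads (percent) in the 18 nt between the windows 5' and 3' of the UGA codon, for 7 genes, with 6 footprint and 6 mRNA libraries as points and the share of the window's length as a black line. For Gpx1 the footprint points lie between 69.7% and 90.2% and the mRNA points between 18.2% and 27.1%.

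Translational efficiency sets footprints against mRNA of the same genotype and diet. In wild type it was lower at 0 than at 0.1 ppm for Sepw1 (3.09-fold, 1.57 to 6.76), Sephs2 (2.34-fold, 2.23 to 2.46), Sepp1 (1.93-fold, 1.88 to 1.98), Selt (1.68-fold, 1.40 to 2.02), Txnrd1 (1.66-fold, 1.51 to 1.84) and Txnrd3 (1.62-fold, 1.11 to 2.36), and at 2.0 ppm it was 1.5-fold higher (1.47 to 1.53) for Gpx1. In TrspA37G it was lower at 0 ppm for Gpx3 (4.58-fold, 1.19 to 25.7), Sepw1 (3.69-fold, 1.09 to 19.4), Selk (1.95-fold), Sephs2 (1.86-fold), Gpx4 (1.81-fold), Selt (1.61-fold) and Sep15 (1.58-fold), and higher for Gpx1 (1.97-fold, 1.87 to 2.07), Txnrd2 (1.97-fold, 1.44 to 2.69) and Sepx1 (1.87-fold, 1.73 to 2.03). These Gpx1 values between diets depended on the 18 nt between the windows. Without them TrspA37G Gpx1 at 0 ppm was at log2 -0.11 (-0.27 to 0.05) in place of 0.98 (0.91 to 1.05), so the sign turned and the call ended. In wild type it was at -1.60 (-1.69 to -1.52) at 0 ppm in place of -0.20, past the rule, and at 0.45 (0.41 to 0.49) at 2.0 ppm in place of 0.59 (0.56 to 0.62), below 1.5-fold. Between 2.0 and 0.1 ppm in TrspA37G 0 genes were past the rule. Gpx1 (log2 -0.20), Gpx4 (-0.47), Sepx1 (-0.22), Selh (-0.98), Selk (-0.67), Sep15 (-0.55) and Dio1 (-0.22) were not called in wild type at 0 ppm, nor were Sepp1 (-0.29), Txnrd1 (-0.28), Selh (-0.22) and Dio1 (0.23) in TrspA37G. Sephs2 (1.63-, 2.05- and 2.02-fold) and Sepx1 (1.52-, 3.31- and 3.05-fold) were lower in TrspA37G than in wild type at all 3 diets. Gpx1 was 3.00-fold (2.91 to 3.10) and 4.32-fold (4.19 to 4.47) lower at 0.1 and 2.0 ppm, as were Sepw1 (2.32- and 2.45-fold) and Txnrd2 (2.94- and 2.01-fold). The Gpx1 values between genotypes include the 18 nt as well. At 0 ppm, where Gpx1 was not called, these nt held 88.6% of its footprints in wild type and 90.2% in TrspA37G. The absence of a call there thus rests mostly on reads in these nt. With the footprint density 3' of the UGA divided by mRNA, which leaves them out, Gpx1 was called lower in TrspA37G at all 3 diets. Its density 5' of the UGA at 0 ppm was 359 RPFKM in wild type and 99.5 in TrspA37G, beside mRNA of 893 and 351 RPKM. Gpx3 was 6.35-fold lower (1.73 to 34.9) at 0 ppm, Sepp1 1.52-fold at 0.1 ppm and Sep15 1.63-fold at 2.0 ppm. In these genotype comparisons Gpx4, Txnrd1, Selh, Selk, Selt and Dio1 were not called at any diet. Stress-related genes had 2 of 7 and housekeeping genes 3 of 6 lower at 0 ppm in wild type (medians -0.67 and -0.64). Median-ratio scaling gave 2 lower and 2 higher genes at 0 ppm in wild type in place of 6 and 0, and 0 lower and 5 higher in TrspA37G in place of 7 and 3. It left 1, 5 and 5 of the 3, 6 and 6 genes lower between genotypes, with 1 higher at 0 ppm, and 0 genes lower at all 3 diets. Over the 5' part alone 2 genes were lower at 0 ppm in either genotype, with Sephs2 at log2 0.15 in TrspA37G.

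The readthrough ratio, footprint density 3' of the UGA codon over density 5' of it, was lower at 0 than at 0.1 ppm for 8 of 12 genes in wild type and 7 of 10 in TrspA37G, of which 7 were shared. Sepx1 was 6.22-fold lower (4.36 to 8.88) in wild type and 2.03-fold (1.41 to 2.93) in TrspA37G. Gpx1 was 4.78-fold lower (4.27 to 5.36), with ratios of 0.197 and 0.940, and 2.35-fold lower (1.88 to 2.93) in TrspA37G, with ratios of 0.164 and 0.385. Sephs2 was 2.62-fold (2.33 to 2.95) and 2.64-fold (2.26 to 3.09) lower, Sep15, a partner in protein folding control, 2.57-fold (2.19 to 3.03) and 2.70-fold (2.21 to 3.30), and Gpx4 2.34-fold (2.03 to 2.69) and 2.64-fold (2.24 to 3.11). Dio1 was 2.15-fold (1.63 to 2.84) and 1.59-fold (1.11 to 2.33) lower, and Selt 1.64-fold (1.13 to 2.39) and 3.20-fold (1.95 to 5.31). In TrspA37G, Dio1 was not called against 2.0 ppm, and neither Dio1 nor Sepx1 was called with the 3' density over mRNA. Sepp1 was 2.19-fold lower (2.08 to 2.30) in wild type and at log2 -0.17 in TrspA37G. As Sepp1 has 10 Sec codons and its 3' part starts after the first, its ratio does not describe 1 UGA alone. Seli, with a 3' window of 18 nt, was 2.41-fold higher (1.78 to 3.26) in TrspA37G, at log2 1.27 (0.83 to 1.71). Divided by the mRNA ratio, Seli was at 0.91 (-0.12 to 1.94), still past 1.5-fold but not called, as 18 and 21 mRNA reads 3' of the UGA widened the interval. The wild-type Selt value went from -0.72 (-1.26 to -0.18) to -0.23 (-1.31 to 0.85) on that division, below 1.5-fold and with 28 and 14 mRNA reads 5' of the UGA, and was not called. Selh was at log2 -2.58 in wild type, not called, and in TrspA37G at 0 ppm had 1 read 5' and 0 reads 3' of the UGA, which allows up to 3. Sepw1 has no 5' window and Txnrd1 and Selk have no 3' window, so they have no ratio. In wild type 2 of 3 glutathione peroxidases, 3 of 5 stress-related, 4 of 4 housekeeping and 2 of 4 endoplasmic reticulum genes were lower (medians -1.23, -2.26, -1.29 and -0.45), and in TrspA37G 2 of 3, 3 of 4, 3 of 4 and 2 of 3 (-1.40, -1.32, -1.40 and -1.44). Between 2.0 and 0.1 ppm, Gpx1 was 1.97-fold lower (1.86 to 2.09) in wild type, where its 3' density over mRNA was at log2 0.25, and Selt was 1.71-fold lower (1.2 to 2.45) in TrspA37G, at log2 -0.78 (-1.29 to -0.26). Divided by the mRNA ratio, this Selt value was larger, at -0.97 (-2.04 to 0.10), and was not called because 25 and 16 mRNA reads 5' of the UGA widened the interval. In wild type Selt was at 0.30, and at 1.60 (0.53 to 2.67) after the division. The other genes followed throughout were within the rule there as deposited.

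The 2 parts of the coding sequence differed in how they compared between diets. In wild type, footprints 5' of the UGA at 0 against 0.1 ppm were at log2 0.33 (0.17 to 0.49) for Sephs2, 0.15 for Gpx4, 0.02 for Dio1 and 0.02 for Sepx1, whereas those 3' of it were at -1.06, -1.08, -1.09 and -2.62. Gpx1 had -1.40 and -3.65, and Sepp1 -0.60 and -1.73. In TrspA37G, Sepx1 had 1.07 (0.94 to 1.2) 5' and 0.05 (-0.49 to 0.58) 3' of the UGA, Sephs2 0.00 and -1.41, and Dio1 -1.86 and -2.53. These values within a part shift with the scaling of libraries, and their difference does not.

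**Figure D3:**
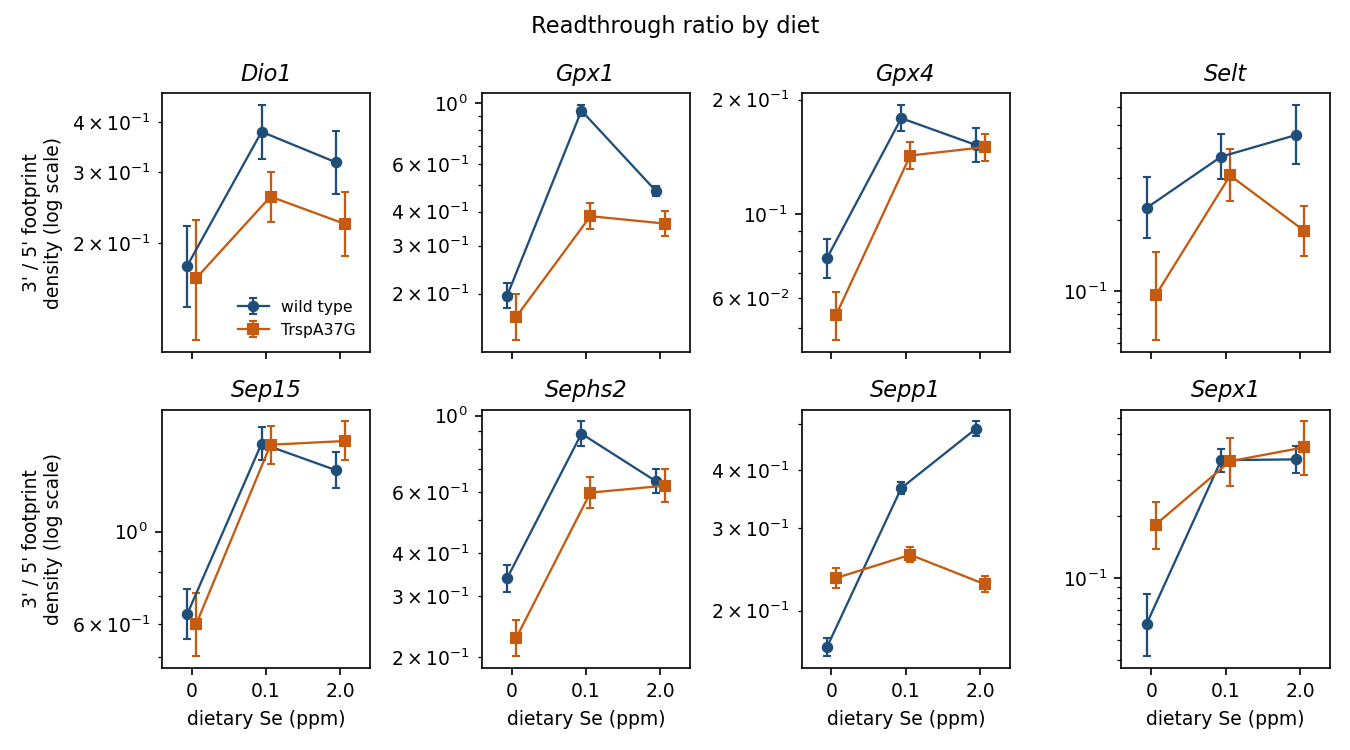
Readthrough ratio (footprint density 3' over 5' of the UGA codon) at 0, 0.1 and 2.0 ppm selenium for 8 genes, 1 panel per gene with its own log axis, in wild type and TrspA37G; points are single libraries and bars 95% counting intervals. Gpx1 in wild type stands at 0.197, 0.940 and 0.477, and Sep15 at 0.633, 1.63 and 1.41.

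Between genotypes, 0 of the 9 genes compared at each diet had a lower readthrough ratio past the rule in all 3. Gpx1 was 2.44-fold lower (2.17 to 2.74) in TrspA37G at 0.1 ppm and within 1.5-fold at 0 (log2 -0.26) and 2.0 ppm (-0.40). Selt was 2.34-fold (1.39 to 3.98) and 2.54-fold (1.73 to 3.72) lower at 0 and 2.0 ppm, and Sepp1 2.14-fold lower (2.03 to 2.26) at 2.0 ppm, with ratios of 0.228 against 0.489. Sepx1 was 3.03-fold higher (1.99 to 4.61) at 0 ppm, and Seli 5.86-fold (3.67 to 9.37) and 2.13-fold (1.41 to 3.22) higher at 0 and 0.1 ppm. Dio1, Gpx1, Gpx4, Selt and Sephs2 had log2 values below 0 at each diet; Gpx4 (-0.50, -0.33 and -0.02), Sephs2 (-0.58, -0.57 and -0.04), Sep15 (-0.08, -0.01 and 0.23) and Dio1 (-0.10, -0.53 and -0.51) were not called, nor was Selh (-2.32 and -0.89 at 0.1 and 2.0 ppm). Of 4 housekeeping genes 0, 0 and 1 were lower, and of the stress-related genes 1 of 3, 1 of 5 and 1 of 5. Divided by the mRNA ratio, Gpx1 was past the rule at 0 (-0.69) and 2.0 ppm (-0.68) too, Seli at 0.1 ppm was at 1.74 in place of 1.09, and Selt at 0 ppm went from -1.23 (-1.99 to -0.47) to -1.0 (-2.29 to 0.30), past 1.5-fold but not called, with 10 and 28 mRNA reads 5' of the UGA. With the 3' density divided by mRNA in place of the 5' density, 5, 6 and 7 genes were lower in TrspA37G, against 1, 1 and 2.

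The response to diet was also set side by side between genotypes, as the difference of log2 ratios with its counting interval. For mRNA between 0.1 and 0 ppm it was larger in TrspA37G for Dio1, by 2.24 (2.08 to 2.4), Seli, by 1.19 (1.04 to 1.33), and Gpx3, by 0.86 (0.00 to 1.73), and smaller for 0 of 20 genes. Between 2.0 and 0 ppm it was larger for Dio1 (1.69), Selt (0.91), Seli (0.85) and Sep15 (0.74) and smaller for Txnrd2 (-0.61). For footprints between 0.1 and 0 ppm it was larger for Gpx3 (3.11), Dio1 (1.79) and Seli (1.35) and smaller for Sepx1 (-1.39), Txnrd2 (-1.13), Gpx1 (-0.88), Txnrd1 (-0.73) and Sepp1 (-0.61). The Gpx3 value rests on 3 footprints in TrspA37G at 0 ppm. Between 2.0 and 0 ppm 6 genes had a larger footprint response, among them Gpx4 (0.84) and Selt (0.85), and 5 a smaller one, among them Gpx1 (-1.40), Sepx1 (-1.48) and Txnrd1 (-1.10). For the readthrough ratio between 0.1 and 0 ppm it was smaller in TrspA37G for Sepx1 (-1.61, -2.35 to -0.88), Seli (-1.46), Gpx1 (-1.03, -1.38 to -0.67) and Sepp1 (-0.96, -1.08 to -0.85) and larger for Selt (0.96, 0.11 to 1.82). With 2.0 in place of 0.1 ppm Selt was at -0.12, Gpx3 mRNA at -0.22, and Sepp1 (-1.59), Seli (-1.93) and Sepx1 (-1.40) were smaller, while Gpx1, at -0.14 (-0.49 to 0.21), was not called. Sephs2 was not past the rule in any of these, nor were Selh, Selk and Sepw1 in mRNA and footprints. These last 3 genes were not compared in the readthrough response.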

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

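All tests in this part were chosen only after the results were seen. Differences between genotypes in their response to diet are described and were not tested, since 1 library for each genotype and diet leaves no residual for them.

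Several genes went opposite ways between diets in the 2 genotypes as deposited, with intervals that excluded no difference in both. Seli mRNA was higher at 0.1 and 2.0 than at 0 ppm in TrspA37G and not in wild type, with response differences of log2 1.19 and 0.85. For Sepx1 footprints the differences were -1.39 and -1.48, and for Txnrd2 footprints at 2.0 ppm -1.58. In translational efficiency they were -1.18 and -1.70 for Gpx1, -1.12 and -1.0 for Sepx1 and -1.52 for Txnrd2 at 0.1 ppm. Without the 18 nt between the windows, Gpx1 efficiency no longer went opposite ways, nor did that of Sepx1 at 0.1 ppm, and the differences were -1.50 and -1.53 for Gpx1 and -0.82 for Sepx1 at 0.1 ppm. After median-ratio scaling, 3 of these 10 results still met this description, Seli at both diets and Gpx1 efficiency at 2.0 ppm. Wild-type Sepx1 footprints were then at log2 -0.39 and -0.55 at 0.1 and 2.0 against 0 ppm, the direction of TrspA37G.

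Reads in the 18 nt between the 5' and 3' parts, taken to end with the UGA codon, lie outside the windows used for the readthrough ratio. Among the 9 genes with at least 10 reads over the coding sequence in every library, the footprint share lay above the mRNA share with separate 95% intervals in 6 of 6 libraries for Gpx1 (lowest share 69.7%), Sepx1 (36.8%), Sep15 (2.43%), Sephs2 (1.55%) and Sepp1 (1.28%). The lowest shares of Sep15 and Sepp1 lie below their shares of the length (4.20% and 1.66%), and the mRNA shares of Sep15 were 0.392% or less. Dio1 and Selt were above in 6 of 6 libraries too, with separate intervals in 3, and so was Selh, which has fewer reads. Gpx4 (1.05% to 3.16% of footprints, 4.30% to 6.34% of mRNA reads) had the smaller share in footprints in 6 of 6 libraries and Seli (1.37% to 3.28%, 3.05% to 5.66%) in 5 of 6.

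Dio1, Seli and Txnrd2 mRNA were called lower at 0 ppm in TrspA37G and not in wild type. Txnrd2 was left out of the tests below. Its TrspA37G footprints were not lower, at 5.50 RPFKM at 0 and 4.60 at 0.1 ppm. Nothing here argues against a fault of 1 library for Txnrd2. A single scaling factor of the library was argued against for Dio1, whose response difference after median-ratio scaling was 2.03 (1.88 to 2.19). It stays open for Seli: the difference was 0.98 (0.83 to 1.12), but the TrspA37G value itself went from -0.97 (-1.09 to -0.86) to -0.53 (-0.64 to -0.42), below 1.5-fold, as the scaling removed a median of -0.44, and the call ended. A fault of 1 library was argued against for Dio1 and Seli, which had a response difference past the rule in both mRNA and footprints as deposited. Another difference between the livers sampled may still be the cause, and cannot be told apart from genotype and diet with 1 library per group.

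The excess of Gpx1 and Sepx1 footprints in the 18 nt may come from a bias present in both kinds of library, from ribosomes waiting at the UGA codon, or both. A bias of equal size in both as the whole cause was argued against for Gpx1, where the lowest log2 odds ratio of footprints against mRNA was 2.92 (2.83 to 3.02), and stays open for Sepx1, at 0.76 (0.54 to 0.98), since singling these genes out for an excess fixed its sign and only a size past 1.5-fold was counted. The 18 nt are taken to hold the UGA, which was not tested. If less selenium left more ribosomes there, footprints in them relative to those 5' should be higher at 0 than at 0.1 ppm. This was so for Gpx1, at log2 0.16 (0.03 to 0.29) in wild type and 0.54 (0.31 to 0.78) in TrspA37G (0.74 and 1.07 against 2.0 ppm), and not for Sepx1 in wild type, at -0.72 (-0.84 to -0.61), which was nearer 0 against 2.0 ppm, at -0.16 (-0.29 to -0.03). Sepx1 in TrspA37G, at 0.03 (-0.16 to 0.23), left it open, and a bias of unequal size or specific to footprint libraries was not tested.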

How the results depend on the processing

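The alternatives without the 18 nt between the windows, with mRNA over the coding window, with readthrough divided by the mRNA 3' to 5' ratio and without the TrspA37G 0 ppm library were chosen only after seeing the data. Unless a reason is given, the cause was not tested. A floor of 30 reads or no floor moved 0 of 66 counts by over 1.5 times, and a pseudocount of 1 RPKM moved 1, footprints lower in TrspA37G at all 3 diets, from 6 to 3. The labels give no replicate numbers to pair by. The genotypes could have been paired by diet; that was left out, and an exact two-sided test exchanging labels within diets cannot give a p below 0.25. Depth limits genes such as Selh, Gpx3 and Sepw1, whose intervals at 0 ppm are wide.

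Median-ratio scaling moved 26 of 49 counts, and of 500 gene values 276 moved beyond their counting interval and 115 turned sign, 9 of them called as deposited and 7 others called only after the scaling. By construction it removes what the listed selenoproteins share. Genes lower at 0 against 0.1 ppm went from 6 to 3 for TrspA37G mRNA, from 11 to 5 and 14 to 3 for wild-type and TrspA37G footprints, and from 6 to 2 and 7 to 0 for translational efficiency. Genes higher at 2.0 ppm in wild type went from 3 to 1 (footprints) and 1 to 0 (efficiency), and those lower in TrspA37G at all 3 diets from 6 to 1 (footprints) and 2 to 0 (efficiency). Of the footprint values called as deposited, those at 0 against 0.1 ppm changed sign for Selt in wild type (0.08) and for Gpx1 (0.38), Gpx4 (0.39), Sephs2 (0.03) and Sepp1 (0.35) in TrspA37G, and between genotypes at 0 ppm for Seli (0.20), Selo (0.01), Sep15 (0.13) and Sepx1 (0.09). Turned and called higher were Gpx4, Selo and Sels in wild type and Sels and Txnrd1 in TrspA37G at 0 ppm, and Selk and Sepp1 between genotypes at 0 ppm.

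A 2-fold size rule moved 21 of 66 counts, since fewer ratios reach it. At 0 ppm TrspA37G mRNA went from 6 to 3 lower, wild-type footprints from 11 to 7, and efficiency from 6 to 2 in wild type and 7 to 2 in TrspA37G. At 2.0 ppm in wild type higher genes went from 1 to 0 (mRNA), 3 to 1 (footprints) and 1 to 0 (efficiency). Efficiency lower at all 3 diets went from 2 to 0. Differing responses went from 5 to 1 for mRNA at 2.0 ppm, from 8 to 5 and 11 to 6 for footprints at 0.1 and 2.0 ppm, and from 5 to 3 for readthrough at 0.1 ppm.

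With 2.0 ppm as reference, genes lower at 0 ppm in wild type went from 4 to 7 (mRNA) and 6 to 10 (efficiency), and differing responses from 3 to 5 (mRNA) and 5 to 3 (readthrough). Txnrd2 mRNA in TrspA37G was then at 0.02, and the response differences of Gpx3 mRNA and Selt readthrough at -0.22 and -0.12. Turned and newly called were wild-type Gpx3 at 0 ppm, in mRNA (0.23 to -0.63) and footprints (0.29 to -0.85), and the Txnrd2 mRNA response difference (0.39 to -0.61).

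Over the 5' part of the coding sequence, footprints lower at 0 ppm went from 11 to 6 in wild type and 14 to 8 in TrspA37G, and efficiency from 6 to 2 and 7 to 2. Higher at 2.0 ppm were 1 in place of 0 (TrspA37G footprints) and 2 in place of 1 (wild-type efficiency), and efficiency lower at all 3 diets went from 2 to 1. Sephs2 changed sign at 0 ppm, in wild-type footprints (0.33) and TrspA37G efficiency (0.15). Selt footprints between genotypes at 2.0 ppm turned from -0.15 to 0.66 (0.24 to 1.09) and were then called higher in TrspA37G. Without the 18 nt between the windows, genes higher at 2.0 ppm in wild type went from 3 to 1 (footprints) and 1 to 0 (efficiency), and Gpx1 efficiency in TrspA37G at 0 ppm turned from 0.98 to -0.11, as most Gpx1 footprints lie in them. With mRNA over the coding window, efficiency higher at 2.0 ppm in TrspA37G went from 0 to 1. Without the TrspA37G 0 ppm library, efficiency was lower at both other diets for 5 genes in place of 2, as fewer diets must be passed.

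Readthrough as 3' density over mRNA was lower in TrspA37G at all 3 diets for 2 genes in place of 0, and Gpx1 at 2.0 against 0.1 ppm in wild type was at 0.25. Sepx1 between genotypes at 2.0 ppm turned from 0.20 to -1.51 (-1.96 to -1.06) and was then called lower. Divided by the mRNA ratio, 1 gene in place of 0 was higher at 2.0 ppm in wild type and 1 in place of 0 lower in TrspA37G at all 3 diets. Leaving out genes with a late UGA and Sepp1 moved 4 of 15 counts downwards, since Seli and Sepp1 are then absent.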

Other observations

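All tests in this part were chosen only after the results were seen.

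Sels, a membrane protein of the endoplasmic reticulum, and Selm, a resident of its lumen, were not past the rule in any of the mRNA and footprint comparisons against 0.1 ppm or between genotypes as deposited. Selm had few reads, with 8 to 17 footprints per library, so this does not show stable values. Its wild-type mRNA was at 0.809 RPKM at 0 and 1.66 at 0.1 ppm. Against 2.0 ppm, its TrspA37G footprints were called lower at 0 ppm. Selo, a mitochondrial pseudokinase, was lower in TrspA37G at 0 ppm in both mRNA (1.55-fold) and footprints (1.94-fold). Sepp1 had the most mRNA of the listed genes, at 2630 RPKM in wild type and 2025 RPKM in TrspA37G at 0.1 ppm, followed by Gpx1 in both.

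The readthrough ratio was lower at 0 than at 0.1 ppm in 8 genes in wild type and 7 in TrspA37G, which may reflect fewer ribosomes passing the UGA codon with less selenium. Uneven coverage along the mRNA was argued against for these genes as a set: divided by the mRNA ratio, their median log2 difference was still -1.13 (-1.31 to -1.01) and -1.24 (-1.47 to -0.90). Taking the median over genes called for a lower ratio favours a low value. The readthrough interval lay below that of the mRNA ratio for 7 of 8 genes in wild type and 4 of 7 in TrspA37G. A higher 5' density alone was argued against in wild type by lower 3' densities in 8 of 8 genes, although 3' values shift with library scaling. In TrspA37G the 3' density was lower in 6 of 7 genes. It was argued against there for these 6 and not for the set. Choosing genes for a lower ratio also favours a lower 3' density. For Sepx1 in TrspA37G the 3' density was at log2 0.05 (-0.49 to 0.58), as a higher 5' density alone would give. A loss of footprints towards the 3' end of every mRNA could also give the pattern and stays open, since 0 genes without a Sec codon are listed.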
